A study of Mus musculus with 12 samples.

How the data were processed

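The series measured gene expression by 3' mRNA sequencing (QuantSeq) in fetal liver cells of C57BL/6N mice taken at embryonic day 13.5 to 14.5 and cultured with stem cell factor (150 ng/ml), interleukin 3 (10 ng/ml) and interleukin 6 (10 ng/ml). Per the labels, cells were transduced by retrovirus with NUP98-KDM5A or with 1 of 2 artificial fragments, artFG or artAA, joined to the C-terminal part of KDM5A, and then sorted, and unmodified cells served as the comparison. The labels give 4 groups of 3 libraries, and each library was assigned to its group by its title and description, with replicate numbers 1 to 3. Nothing in the labels says whether replicates are separate animals, cultures or transductions, or gives a batch, so p-values measure the spread between these libraries alone.

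Per the submitters' processing notes the tools named are FastQC, STAR, SAMtools, featureCounts and DESeq2, with GRCm38 (mm10) as the genome. Their versions, order, the gene annotation, the strand setting and any filter are not given in the sources used here. The authors deposited 1 table of 24454 gene symbols by 12 libraries whose values are a normalized expression signal in linear scale, made before deposit by dividing gene read counts by a factor per library. This was checked on the file: dividing out the factor gave whole numbers for 100% of values within 1e-06 (largest deviation 2.56e-09), and size factors recomputed by the median-of-ratios method in DESeq2 equalled those recovered. The table also held 2 trailing columns that belong to no sample, with 1 cell filled, which were not used here, and 0 per-sample columns without a sample. The raw sequencing reads were not analysed here, so alignment, assignment to genes and the share of construct reads under Kdm5a or Nup98 could not be examined.

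Depth, as reads assigned to genes, was 3446762, 5972142 and 4184644 in unmodified replicates 1 to 3, 4814351, 4232591 and 4150868 with NUP98-KDM5A, 8921585, 6225382 and 7436761 with artAA-KDM5A, and 8503064, 2960551 and 3613025 with artFG-KDM5A. Size factors ran from 0.622 to 1.84. The chi-square of replicates per degree of freedom, which is near 1 for counting error alone, lay between 3.97 and 100.2 across pairs of libraries of a group, so the spread between libraries exceeded counting error. Bounds written as at least N-fold set a group without reads at 3 reads over its 3 libraries and cover counting error only, and for a group with 1 to 3 reads no fold of means is given. The fitted log2 change of a gene with 0 to 3 reads in a group depends on the pseudocount and is neither a bound nor a measured size. Gene symbols were matched to GENCODE M21 for coordinates on GRCm38, and 23513 (96.2%) had a single match and 50 several.

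Genes with a value of at least 10 in at least 3 libraries were tested (11009). A linear model with 4 group means was fitted to log2(value + 1) over the 12 libraries with limma 3.58.1 in R 4.3.3, with moderation of variances along the mean, and 6 comparisons between groups were tested 2-sided. P-values were adjusted by Benjamini and Hochberg within each comparison, and a gene passed at an adjusted p under 0.05. Log2 changes are on the log2(value + 1) scale, which understates changes of low genes, while folds are ratios of group means of normalized counts. SD rests on the 3 libraries of a group, and SE on the moderated spread estimated over the 12 libraries.

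A set of 30 gene lists was fixed before the data were examined, as were the comparisons, the filter, the test, the rule for named genes and the alternatives. Lists with at least 3 tested members were tested with camera (limma) at an inter-gene correlation of 0.01 and again with an estimated correlation, and with fry beside it, and these p-values were adjusted over 168 tests. Of these 88 passed, and 50 with an estimated correlation. The HOXC and HOXD genes had 0 of 18 members tested, and of 15 mitochondrially encoded transcripts 0 are in the table. Counts of list members below are of those tested. Tested were 4 of 11 HOXA, 3 of 10 HOXB and 9 of 23 lymphoid genes. Of the stromal and endothelial list 3 of 18 were tested, and of the fetal hepatocyte list 3 of 20. For each list the genes passing over all tested genes are given, and the number that pass when p-values are adjusted over the list alone. Because group means are shared, comparisons with a common group are not independent of each other.

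The genes named in the text were taken from a set fixed by rule, not all of which are printed. In each comparison the set holds the 6 largest positive and 6 largest negative log2 changes among genes that passed, with a mean of at least 50 over the 12 libraries and no overlap between the groups (10% of genes separate in this way by chance with 3 against 3), leaving out predicted models and pseudogenes. To these are added up to 4 members with the smallest adjusted p of each list with a gene that passed, and always Hoxa7, Hoxa9, Hoxa10, Meis1, Pbx3, Cdk6, Kit, Cd34, Flt3, Mpo, Elane, Cpa3, Gata1, Itgam, Cebpa, Irf8, Nup98 and Kdm5a. Outside this set, some members of a list that moved against its majority are also named, and a result of 1 gene that meets this rule is not reported here. A p that misses the threshold does not show that values did not differ.

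Pairs of comparisons without a common library were correlated across genes, and for pairs that share the unmodified libraries the correlation given by sharing alone was taken from 100 simulations. Genes called for NUP98-KDM5A against unmodified cells were tested as sets in artFG-KDM5A against artAA-KDM5A with camera. The test per gene and camera were run on simulated data with 200 of 11009 genes changed. The test per gene recovered 46% to 59% of 4-fold changes and 5% to 12% of 2-fold changes with 2 or 3 false calls per comparison. Of 30 unchanged lists 0 or 1 had a camera p under 0.05. Simulated genes varied independently with the same dispersion in every group, and camera ran without the trend of variances. These rates therefore test neither the preset inter-gene correlation nor an uneven spread between groups. Alternatives were a pseudocount of 0.5 or 5, no filter or a filter at 50, equal totals, TMM factors or quantile normalization, a fit of the compared groups alone, replicate number as a block, robust moderation, weights per library, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 Wald tests on whole reads, an added threshold of 1 on the log2 change, and leaving out each library. Replicate numbers were not used as pairs, since residuals of same-number libraries correlated between −0.223 and 0.156, with 1 of 18 pairs above 0.1. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.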

Results

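Fetal liver cells of C57BL/6N embryos carried NUP98-KDM5A or 1 of 2 artificial fusions of the C-terminal part of KDM5A, artFG-KDM5A and artAA-KDM5A, and were compared with unmodified cells in 3 libraries per group. No group carried an empty vector, so differences from unmodified cells are not separated from effects of transduction and sorting. Values are normalized read counts, given as mean ± SD of 3 libraries unless stated otherwise. Kdm5a, the histone demethylase gene whose C-terminal part the constructs share, read 1037, 935.5 and 913.7 in the unmodified libraries, 1571, 1591 and 1798 with NUP98-KDM5A, 3498, 2377 and 3414 with artAA-KDM5A, and 24310, 18720 and 17820 with artFG-KDM5A. Against unmodified cells this was a rise of 1.72-fold for NUP98-KDM5A (adjusted p = 0.00708), 3.22-fold for artAA-KDM5A (adjusted p = 0.000379) and 21.1-fold for artFG-KDM5A (adjusted p = 1.14e-08). The counts do not separate construct from endogenous Kdm5a, and how far construct transcripts are counted under this gene could not be examined. Nup98, a nucleoporin gene, lay at 91.4 ± 17.0 in unmodified cells, 134 ± 35.5 with NUP98-KDM5A, 92.6 ± 47.6 with artFG-KDM5A and 79.0 ± 18.6 with artAA-KDM5A, and passed the test in no comparison (lowest adjusted p = 0.188, NUP98-KDM5A against artAA-KDM5A). Whether transcripts of the NUP98-KDM5A construct are counted under Nup98 at all in 3' sequencing could not be examined. The Nup98 counts therefore do not show how much of the fusion was expressed.

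The unmodified cultures were rich in mast cell transcripts. Cpa3, a mast cell carboxypeptidase, reached 165200 ± 3856, the tryptase gene Tpsb2 134900 ± 6153 and the chymase gene Cma1 62770 ± 6154. The HOXA cluster genes Hoxa9 and Hoxa7 lay at 3.82 ± 0.991 and 0.536 ± 0.928, and the granule enzyme gene Mpo at 8.46 ± 5.05. Libraries held between 2960551 and 8921585 reads, and the ribosomal RNA precursor Rn45s took between 6.26% and 19.7% of them. Pearson's r across genes between libraries of a group was 0.969 to 0.973 in unmodified cells, 0.973 to 0.980 with NUP98-KDM5A and 0.943 to 0.978 with artAA-KDM5A. In artFG-KDM5A it was 0.960 between replicates 1 and 3, and 0.818 and 0.820 between replicate 2 and these. That replicate listed 15894 of 24454 genes at 0, against 11168 to 12498 in the other 11 libraries, and against 11474 to 12947 when these were thinned to its 2960551 reads. Of 5088 genes at 100 or more in both other artFG-KDM5A libraries, 71 (1.40%) were at 0 in replicate 2, while every other library had 0 such genes. A 0 in that library is therefore given below as a listed value, and the number of genes called in each comparison is also given without it.

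**Figure D1:**
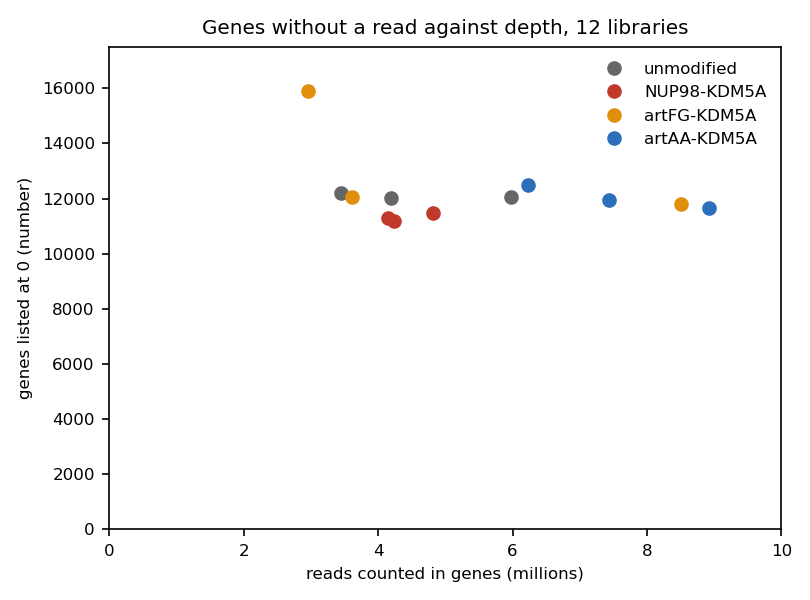
Genes listed at 0 (vertical axis) against sequencing depth (horizontal axis, total reads), 1 point per library and 1 colour per group. The artFG-KDM5A replicate 2 stands at 15894 genes, and the other 11 libraries lie between 11168 and 12498.

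With NUP98-KDM5A the 4 tested HOXA genes of the 11 listed, transcription factor genes of blood progenitors, rose. These 4 lay under the filter in unmodified and artAA-KDM5A cells. They were tested only because they were high with NUP98-KDM5A or artFG-KDM5A. Their number higher against unmodified or artAA-KDM5A cells, here and below, is therefore in part set by the filter. Hoxa9 rose 282-fold to 1079 ± 120 (adjusted p = 6.07e-08), Hoxa5 rose from 1.48 ± 1.43 to 112 ± 12.4 (adjusted p = 1.84e-05), and Hoxa7 from 0.536 ± 0.928 to 305 ± 26.8. Hoxa10 read 190 ± 13.8 against 0 in every unmodified library, at least 151-fold higher. The cluster spans 52155590 to 52260880 on chromosome 6 of GRCm38. Of 3 HOXB genes, Hoxb3 (51.5 ± 1.89 against 2.40 ± 2.11) and Hoxb5 (19.5 ± 5.09, at least 15.5-fold higher than the 0 of unmodified cells) rose, and Hoxb4 did not pass. The HOXA list moved up as a set (4 of 4 higher, 4 adjusted over the list alone, adjusted p = 7.03e-07), while the HOXB list (2 of 3 higher, 2 adjusted over the list alone, adjusted p = 0.0166) gave adjusted p = 0.0927 with an estimated correlation. Hoxb3 and Hoxb5 lay under the filter in unmodified and artFG-KDM5A cells and were tested because they were high with NUP98-KDM5A. The HOXB count and list test are therefore also in part set by the filter. Among 24 genes associated with NUP98-fusion and MLL-fusion leukaemia, 15 rose, 3 fell and 6 did not pass (15 and 4 adjusted over the list alone, adjusted p = 4.16e-07). Hmga2, a fetal chromatin protein gene, rose 96.7-fold to 1478 ± 22.4, Sox4 rose 95.5-fold to 830 ± 49.0 and the kinase gene Cdk6 rose 2.88-fold to 3025 ± 167. The receptor gene Flt3 reached 199 ± 14.6 against 0.317 ± 0.548 (adjusted p = 3.26e-06). The 3 that fell were Zeb2, Pbx3 (4.06-fold to 27.2 ± 7.05) and the HOXA cofactor gene Meis1 (212 ± 36.5 to 111 ± 26.9, adjusted p = 0.0275). The Meis1 call was lost when any of 5 libraries was left out, with the highest adjusted p = 0.118 without NUP98-KDM5A replicate 3. Stem and progenitor genes went both ways, with 9 of 26 higher and 9 lower (9 and 10 adjusted over the list alone, adjusted p = 0.776). The fetal RNA-binding protein gene Lin28b (108 ± 13.1 against 0, at least 85.5-fold) rose, and Kit fell 9.39-fold and Cd34 4.00-fold. The median of this list, −0.11 on the log2 scale beside a mean of 1.12, turned to 0.22 with libraries scaled to equal totals.

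Granulocyte genes rose with NUP98-KDM5A and mast cell genes fell. Of 23 neutrophil granule and granulocyte genes 22 rose and 1 did not pass (22 adjusted over the list alone, median log2 change 6.83, or 6.59 with the member at 0 set at its bound, adjusted p = 8.41e-24). Mpo rose 757-fold to 6403 ± 199, the neutrophil proteinase gene Prtn3 from 6.38 ± 5.77 to 4523 ± 343, and the calprotectin genes S100a8 and S100a9 rose 582-fold and 461-fold to 13890 ± 268 and 16190 ± 458. The granulocyte factor gene Cebpa rose 57.3-fold (adjusted p = 3.32e-05), the integrin gene Itgam 13.4-fold, and the neutrophil elastase gene Elane from 2.85 ± 2.84 to 1719 ± 169. Of 10 eosinophil genes 9 rose (9 and 1 lower adjusted over the list alone, adjusted p = 9.56e-08), led by the major basic protein gene Prg2, which rose from 5.28 ± 5.31 to 6125 ± 84.3. Of 23 monocyte and macrophage genes 16 rose and 7 did not pass (18 higher and 1 lower adjusted over the list alone, adjusted p = 4.05e-10), among them Ccr2 (21.1-fold), Irf8 (18.9-fold) and F13a1 (185-fold). Erythroid genes rose in 9 of 14 cases and Gata1 alone fell (9 and 1 adjusted over the list alone, adjusted p = 0.00276), with the erythroid factor gene Klf1 at 58.9 ± 8.53 against 1.17 ± 1.02. Of 25 mast cell and basophil genes 18 fell, 4 did not pass and 3 rose (20 and 3 adjusted over the list alone, median −2.88, adjusted p = 2.83e-11). Cpa3 fell 8.61-fold to 19180 ± 1341, Cma1 fell 10.9-fold and the IgE receptor gene Fcer1a fell 39.6-fold. The 3 that rose were Mcpt8, a basophil protease gene (317 ± 20.7 to 992 ± 22.6), Mcpt1 and Prss34. Cholesterol synthesis genes fell in 13 of 22 cases and 9 did not pass (13 and 1 adjusted over the list alone, adjusted p = 4.02e-06), Hmgcs1 by 2.85-fold and Lss by 3.64-fold. MYC and ribosome biogenesis genes rose in 8 of 28 cases (11 adjusted over the list alone, adjusted p = 0.00352, and adjusted p = 0.104 with an estimated correlation), among them Npm1 (2.60-fold). With equal totals 17 of these rose, and 13 without artFG-KDM5A replicate 2. The genes of the leukaemia-associated list that fell numbered 1 with equal totals.

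In all, 2634 of 11009 genes differed between NUP98-KDM5A and unmodified cells by limma, 1387 higher and 1247 lower, of which 1184 and 940 by at least 2-fold. Without artFG-KDM5A replicate 2, a library outside this comparison that shares its estimate of spread, the count was 4617. The count was higher still with only the compared groups fitted or with weights per library, as given below. Of the called genes 52.7% were higher, and with libraries scaled to equal totals 72.6%. The median log2 change of all genes was 0.0219, 0.347 with equal totals and −0.0401 after quantile normalization.

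**Figure D2:**
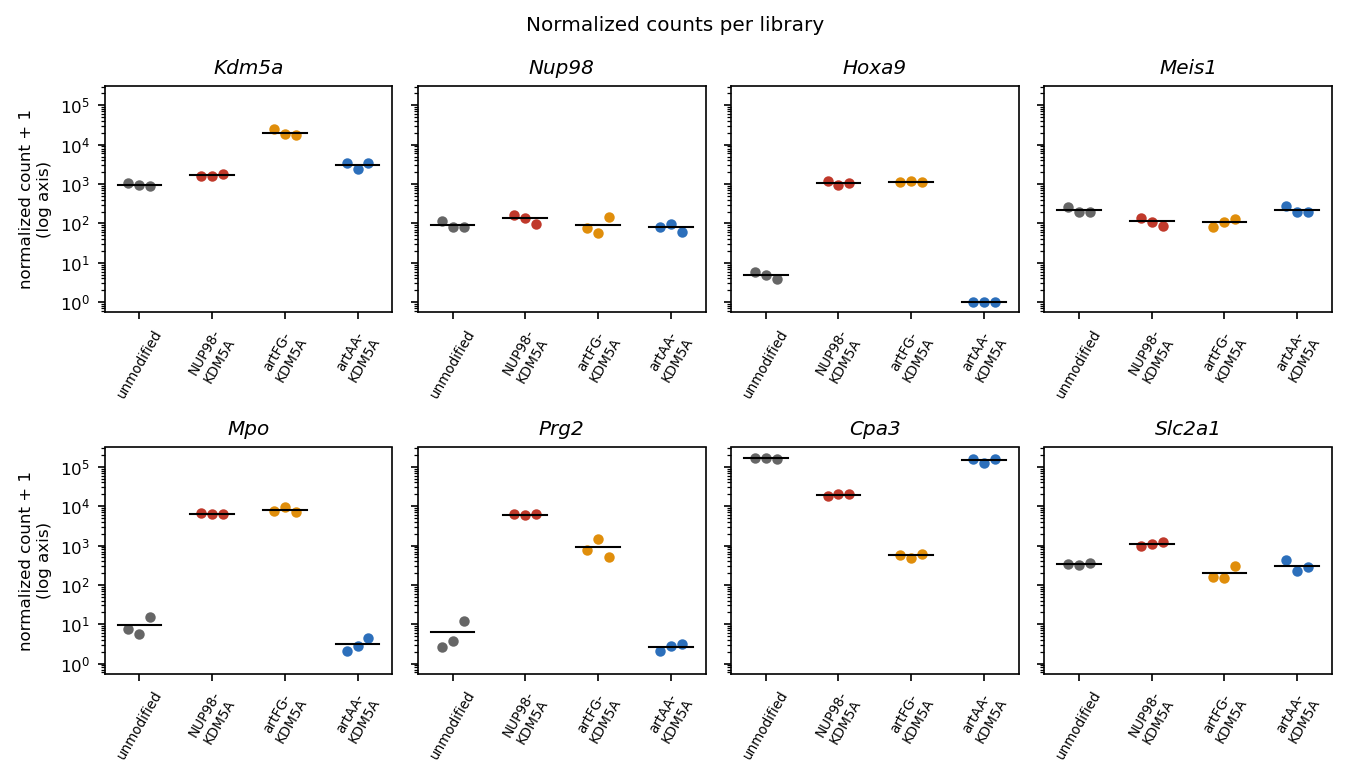
Normalized read count plus 1 on a log axis for 8 genes, with 1 dot per library and a black line at the mean of each of 4 groups. Hoxa9 reached 1079 with NUP98-KDM5A and 1134 with artFG-KDM5A and read 0 in the artAA-KDM5A libraries, while Cpa3 stayed at 146700 with artAA-KDM5A.

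With artFG-KDM5A the HOXA genes rose as well, 4 of 4 tested (4 adjusted over the list alone, adjusted p = 7.31e-06). Hoxa9 rose 297-fold to 1134 ± 58.7, Hoxa5 reached 162 ± 22.2, Hoxa7 read 351 ± 154, and Hoxa10 (139 ± 71.1) was at least 111-fold higher. Of the HOXB list 2 of 3 fell (2 adjusted over the list alone, adjusted p = 0.491), with a median of −1.59, or −1.40 with Hoxb3 at its bound, that turned to 0.01 after quantile normalization. These were Hoxb4 (61.0 ± 18.2 to 11.6 ± 12.9, adjusted p = 0.0148) and Hoxb3, which is listed at 0 (adjusted p = 0.0264). Both calls were lost without unmodified replicate 1 (adjusted p = 0.0545 and 0.107), 1 of the list fell after quantile normalization, and the log2 change of Hoxb4 went from −3.22 to −1.88 without artFG-KDM5A replicate 2. The leukaemia-associated list again had 15 of 24 higher and 3 lower (15 and 3 adjusted over the list alone, adjusted p = 4.99e-07), with Hmga2 at 2368 ± 962 and Sox4 at 887 ± 377. Meis1 fell to 108 ± 25.2 (adjusted p = 0.0137, and 0.0634 without unmodified replicate 1). Of 23 granulocyte genes 20 rose and 3 did not pass (20 adjusted over the list alone, median 6.01, adjusted p = 2.32e-17). Mpo rose 957-fold to 8103 ± 1475, S100a8 817-fold to 19480 ± 7564 and S100a9 563-fold to 19790 ± 3632. The granulocyte factor gene Cebpe reached 587 ± 66.7 from 0.536 ± 0.928. Eosinophil genes rose in 4 of 10 cases (3 adjusted over the list alone, adjusted p = 0.00171), and in 8 after quantile normalization and 7 without artFG-KDM5A replicate 2. Among these Prg2 rose to 910 ± 473. Monocyte and macrophage genes split, with 12 of 23 higher and 5 lower (12 and 5 adjusted over the list alone, adjusted p = 0.00359, and adjusted p = 0.187 with an estimated correlation). Lyz2, a lysozyme gene, rose 23.7-fold, and the 5 that fell were Mrc1, Cx3cr1 and the complement genes C1qa, C1qb and C1qc.

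Mast cell genes fell further with artFG-KDM5A, 24 of 25 with Prss34 not passing (24 adjusted over the list alone, median −5.68, adjusted p = 1.89e-15). Cpa3 fell 290-fold to 569 ± 65.9, Cma1 503-fold, Tpsb2 1150-fold to 118 ± 34.4, and Tpsab1 is listed at 0 in the 3 libraries, at least 929-fold lower. Kit fell 13.8-fold and Gata1, a factor of mast and erythroid cells, 6.31-fold. MYC and ribosome biogenesis genes rose in 21 of 28 cases and fell in 1, Ldha (22 and 1 adjusted over the list alone, adjusted p = 2.48e-10), with Utp20 4.41-fold and Nop56 3.81-fold higher. Glycolysis and hypoxia genes fell in 18 of 23 cases and 2, Hk2 and Egln3, rose (18 and 2 adjusted over the list alone, adjusted p = 0.000156). Ero1l fell 6.22-fold, the mitophagy gene Bnip3 15.4-fold and the aldolase gene Aldoc 14.9-fold. Cholesterol synthesis genes fell in 14 of 22 cases and 8 did not pass (16 adjusted over the list alone, adjusted p = 0.00145), Hmgcs1 by 4.31-fold. Cell cycle genes rose in 11 of 32 cases and fell in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.00048, and adjusted p = 0.123 with an estimated correlation), among them the helicase gene Mcm5 (3.03-fold) and the replication licensing gene Cdt1 (4.85-fold). Cytokine receptor and STAT signalling genes fell in 11 of 22 cases and rose in 2, Csf2ra and Il6ra (12 and 2 adjusted over the list alone, adjusted p = 0.0304, and adjusted p = 0.315 with an estimated correlation). Csf2rb2, a receptor subunit of IL-3, fell 50.0-fold. Polycomb and KDM5 chromatin genes rose in 7 of 26 cases and fell in 2, Ezh1 and Cdkn2a (6 and 2 adjusted over the list alone, adjusted p = 0.0238, and adjusted p = 0.187 with an estimated correlation). With equal totals 8 cholesterol synthesis genes fell and 17 cell cycle and 11 polycomb and KDM5 genes rose.

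Beside these changes, the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty fell with artFG-KDM5A. Ddx3y read 2.89, 1.42 and 2.31 in its 3 libraries, against 346 ± 13.6 in unmodified cells, 177 ± 21.5 with NUP98-KDM5A and 245 ± 24.1 with artAA-KDM5A. The sex-linked list had 4 of 5 lower (4 adjusted over the list alone, adjusted p = 0.00683, and adjusted p = 0.0508 with an estimated correlation), and Xist, the X-inactivation RNA, read 645, 174 and 948 with artFG-KDM5A against 271 ± 63.6. The imprinted fetal genes H19 and Igf2 fell from 8566 ± 343 and 2635 ± 262 to 9.42 ± 12.98 and 2.12 ± 2.33. No label gives the sex or the embryos from which a library came, so differences of artFG-KDM5A from the other groups, and their p-values, are not separated from a difference in the sex or source of the cells. Ddx3y, as 1 of the 5 sex-linked genes, also passed lower with NUP98-KDM5A than in unmodified cells (limma adjusted p = 0.0249). That call was lost when any of 6 libraries was left out, with the highest adjusted p = 0.103 without NUP98-KDM5A replicate 3. The labels do not show that sex and source match between the other groups either. The difference between artFG-KDM5A and unmodified cells covered 4483 genes, 1766 higher and 2717 lower, of which 1305 and 2336 by at least 2-fold, and 5588 without artFG-KDM5A replicate 2. Of these 39.4% were higher, 56.3% with equal totals and 54.7% after quantile normalization. The median log2 change of all genes was −0.302, 0.0545 with equal totals and 0.111 after quantile normalization.

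With artAA-KDM5A HOXA genes did not rise and some granulocyte genes fell. Hoxa9 was listed at 0 in the 3 libraries, at least 5.61-fold below the 3.82 of unmodified cells (adjusted p = 0.0026), while Hoxa5, Hoxa7 and Hoxa10 did not pass (1 of 4 lower, 1 adjusted over the list alone, adjusted p = 0.0904). Of 23 granulocyte genes 2 rose and 4 fell (3 and 6 adjusted over the list alone, adjusted p = 0.462), and the median of −0.32, or −0.33 with members at 0 set at their bounds, turned to 0.08 after quantile normalization. Ctsg, a granule protease gene, fell from 699 ± 38.9 to 82.4 ± 54.8 (log2 change −3.37, and −2.67 without artAA-KDM5A replicate 2), the integrin gene Itgam 9.18-fold to 12.9 ± 5.34 and the collagenase gene Mmp8 5.02-fold to 20.8 ± 3.80. S100a9 rose 2.17-fold to 76.4 ± 5.57, Elane read 0.696 ± 1.21 against 2.85 ± 2.84 (adjusted p = 0.625), and Mpo read 2.11 ± 1.23 (adjusted p = 0.0393, and 0.127 without unmodified replicate 3). Cpa3 (146700 ± 16380, adjusted p = 0.818), Kit (7425 ± 851, adjusted p = 0.949), Cd34 (4417 ± 626, adjusted p = 0.693) and Meis1 (219 ± 47.0, adjusted p = 0.999) did not pass. Of 25 mast cell genes 3 rose and 3 fell (3 and 3 adjusted over the list alone, adjusted p = 0.524), with a median of −0.06 that turned to 0.08 with equal totals. After quantile normalization 4 granulocyte genes rose. The mucosal protease gene Mcpt1 rose 89.9-fold to 2193 ± 596 and Mcpt4 2.71-fold, while the histidine decarboxylase gene Hdc fell 8.79-fold to 637 ± 115. Mcpt2 rose 30.6-fold (adjusted p = 0.0339), a call lost when any of 9 libraries was left out, with the highest adjusted p = 0.126 without artAA-KDM5A replicate 2.

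Genes of macrophages, antigen presentation and glycolysis fell with artAA-KDM5A. Of 23 monocyte and macrophage genes 12 fell and 11 did not pass (17 adjusted over the list alone, median −3.04, adjusted p = 2.43e-19), among them the chemokine genes Ccl9 (20.2-fold) and Ccl6 (8.77-fold), the mannose receptor gene Mrc1 (13.1-fold) and the cathepsin gene Ctss (973 to 74.7). Of 9 dendritic cell and MHC class II genes 6 fell (6 adjusted over the list alone, adjusted p = 9.47e-09), H2-Ab1 by 84.9-fold to 2.59 ± 1.65. Glycolysis and hypoxia genes fell in 11 of 23 cases and 12 did not pass (17 adjusted over the list alone, median −1.41, adjusted p = 1.73e-19). The oxygen sensor gene Egln3 fell 9.44-fold, Aldoc 9.14-fold and Pdk1 4.92-fold. NF-kB and inflammatory cytokine genes fell in 6 of 20 cases (10 adjusted over the list alone, adjusted p = 3.99e-10), the chemokine gene Ccl4 by 70.4-fold, and immediate early genes in 6 of 17 (12 adjusted over the list alone, adjusted p = 3.13e-09), Egr3 by 16.0-fold. Interferon response genes fell in 2 of 24 cases, Oasl2 and Rtp4 (11 adjusted over the list alone, adjusted p = 8.96e-09, and adjusted p = 0.191 with an estimated correlation). The Rtp4 call was lost when any of 9 libraries was left out, with the highest adjusted p = 0.127 without artAA-KDM5A replicate 2. Cell cycle genes rose in 5 of 32 cases and 27 did not pass (9 adjusted over the list alone, adjusted p = 9.56e-08), Cdt1 by 3.44-fold, and MYC and ribosome biogenesis genes in 3 of 28 with 1 lower (10 and 1 adjusted over the list alone, adjusted p = 6.66e-09). The lower one was Ldha (adjusted p = 0.00834, and 0.0508 without unmodified replicate 1). The p53 target genes had 2 of 19 higher (3 adjusted over the list alone, median 0.98, adjusted p = 9.96e-07), Ccng1 (2.51-fold) and Ptp4a3 (2.85-fold), the latter with adjusted p = 0.056 without unmodified replicate 1. Kdm5b, a demethylase gene of the KDM5 family, fell 2.42-fold to 227 ± 23.0. Fn1 and Rbp4 were listed at 0 against 25.7 ± 13.9 and 17.5 ± 3.31. Without artFG-KDM5A replicate 2 these counts were 19 glycolysis, 12 NF-kB, 12 immediate early and 16 interferon response genes lower, and 10 cell cycle, 9 MYC and ribosome biogenesis and 6 p53 target genes higher. After quantile normalization 3 dendritic cell and MHC class II genes and 8 interferon response genes fell and 5 p53 target genes rose, and with equal totals 8 cell cycle and 6 MYC and ribosome biogenesis genes rose.

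Among the strongest changes with artAA-KDM5A, Mmp13 was listed at 0 against 178 ± 26.1, at least 261-fold lower, Vldlr, a lipoprotein receptor gene, read 1.08 ± 1.88 against 192 ± 15.9, and Mgarp fell 97.7-fold. Ccl3 read 6.63 ± 5.19 against 420 ± 81.0, and Arg1 7.15 ± 3.86 against 951 ± 148 (adjusted p = 0.0115, and 0.0527 without unmodified replicate 2). The glutamate receptor gene Grm6 rose 5.06-fold to 236 ± 51.1, Crispld2 rose from 1.86 ± 1.20 to 26.4 ± 10.5, Gria3 from 0.474 ± 0.820 to 9.22 ± 0.938, and Lin28b read 7.32 ± 3.18 against 0, at least 5.80-fold higher. The artAA-KDM5A difference covered 377 genes, 78 higher and 299 lower, of which 53 and 264 by at least 2-fold. This count depended on single libraries, and was 201, 213 and 199 without unmodified replicates 1, 2 and 3, 241 and 207 without artAA-KDM5A replicates 2 and 3, and 1336 without artFG-KDM5A replicate 2. The count was also higher with only the compared groups fitted, with weights per library and in DESeq2, as given below. Of the called genes 20.7% were higher, 39.2% with equal totals and 33.5% after quantile normalization. The median log2 change of all genes was −0.0543, 0.0762 with equal totals and 0.0474 after quantile normalization.

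**Figure D3:**
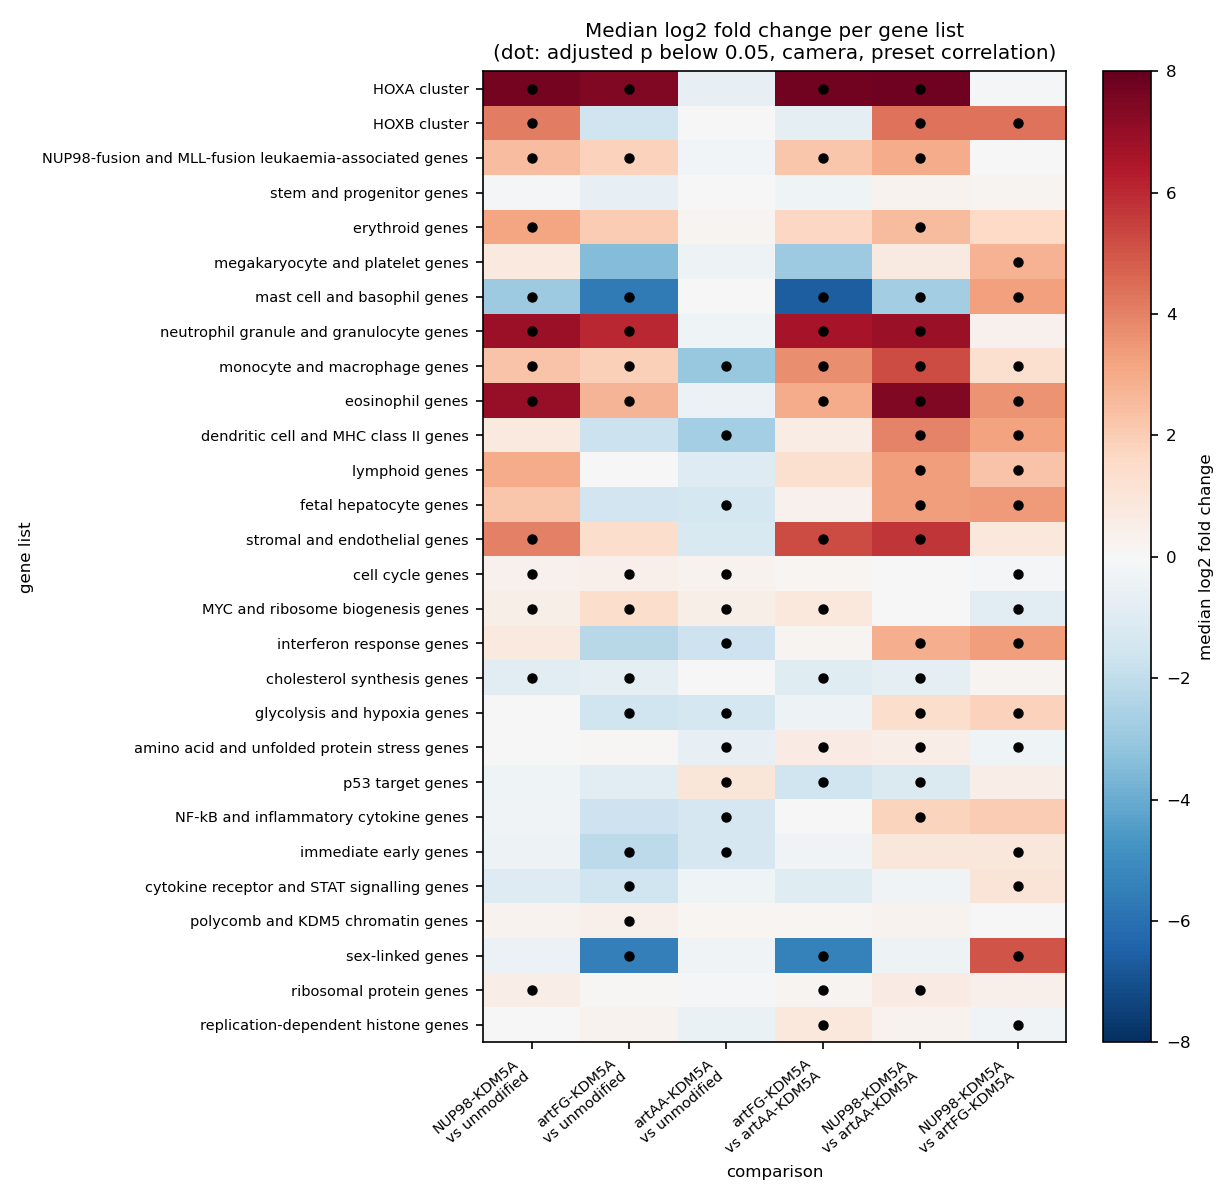
Median log2 fold change (colour) of 28 gene lists in 6 comparisons, with a dot where the camera test gave an adjusted p under 0.05 at the preset correlation. The granulocyte list lies at 6.83 for NUP98-KDM5A, 6.01 for artFG-KDM5A and −0.32 for artAA-KDM5A against unmodified cells, and this last value turned to 0.08 after quantile normalization.

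Set directly against artAA-KDM5A, artFG-KDM5A had higher HOXA genes, 4 of 4 (4 adjusted over the list alone, adjusted p = 3.12e-06), Hoxa9 at least 1670-fold and Hoxa7 at least 516-fold. The myeloid factor gene Mef2c read 913 ± 104 against 1.29 ± 1.40, and leukaemia-associated genes were higher in 14 of 24 cases and lower in 3 (14 and 4 adjusted over the list alone, adjusted p = 7.47e-07). Granulocyte genes were higher in 22 of 23 cases (22 adjusted over the list alone, adjusted p = 1.11e-20), Mpo by 3830-fold and the serum protein gene Hp by 873-fold, and mast cell genes were lower in 22 of 25 (23 adjusted over the list alone, adjusted p = 2.47e-15), Tpsb2 by 1220-fold. Monocyte and macrophage genes were higher in 16 of 23 cases and lower in 1, Cx3cr1 (16 and 1 adjusted over the list alone, adjusted p = 1.46e-10). MYC and ribosome biogenesis genes were higher in 16 of 28 cases (17 adjusted over the list alone, adjusted p = 2.5e-06), amino acid and unfolded protein stress genes in 9 of 22 with 2 lower (9 and 2 adjusted over the list alone, adjusted p = 0.00315), and Slc7a11, a cystine transporter gene, read 135 ± 18.1 against 0.838 ± 0.814. The p53 target genes were lower in 10 of 19 cases (10 adjusted over the list alone, adjusted p = 0.00315, and adjusted p = 0.145 with an estimated correlation), Ccng1 by 5.18-fold and Cdkn1a, a cell cycle inhibitor gene, by 3.39-fold. In all 3955 genes differed, 1614 higher and 2341 lower, of which 1183 and 1995 by at least 2-fold, 5138 genes differed without artFG-KDM5A replicate 2, and the Y-linked genes, H19 and Igf2 differed with them. Of these 40.8% were higher, 52.0% with equal totals and 52.6% after quantile normalization, and the median log2 change of all genes was −0.223, −0.00592 with equal totals and 0.0738 after quantile normalization.

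NUP98-KDM5A had higher HOXA, granulocyte, macrophage and glycolysis genes and lower mast cell genes than artAA-KDM5A. The 4 HOXA genes were higher (4 adjusted over the list alone, adjusted p = 1.29e-06), Hoxa9 at least 1590-fold, as were 22 of 23 granulocyte genes (22 adjusted over the list alone, adjusted p = 1.33e-23) and 22 of 23 monocyte and macrophage genes (22 and 1 lower adjusted over the list alone, adjusted p = 3.38e-17), Mrc1 by 90.3-fold and Ccl9 by 154-fold. Eosinophil genes were higher in 9 of 10 cases and Il5ra was lower (9 and 1 adjusted over the list alone, adjusted p = 8.34e-07), with Prg2 3710-fold higher. Glycolysis and hypoxia genes were higher in 16 of 23 cases (19 adjusted over the list alone, adjusted p = 4.1e-08), Egln3 by 103-fold and Pdk1 by 13.3-fold, and 7 of 9 dendritic cell and MHC class II genes were higher (8 adjusted over the list alone, adjusted p = 2.29e-05), H2-Ab1 by 65.6-fold. Interferon response genes were higher in 15 of 24 cases (18 adjusted over the list alone, adjusted p = 1.17e-06, and adjusted p = 0.264 with an estimated correlation), Parp14 by 4.15-fold. Mast cell genes were lower in 19 of 25 cases and higher in 3, Mcpt8, Hdc and Prss34 (20 and 3 adjusted over the list alone, adjusted p = 1.59e-10), with Kit 10.4-fold and Cpa3 7.65-fold lower. Kdm5a itself was lower than in artAA-KDM5A by 1.87-fold (adjusted p = 0.00291). The comparison called 2886 genes, 1681 higher and 1205 lower, of which 1462 and 860 by at least 2-fold, and 4817 without artFG-KDM5A replicate 2. Of these 58.2% were higher, 69.5% with equal totals and 46.2% after quantile normalization, and the median log2 change of all genes was 0.0203, 0.202 with equal totals and −0.133 after quantile normalization.

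Between NUP98-KDM5A and artFG-KDM5A the HOXA list gave adjusted p = 0.539, and 0 of its 4 genes passed in limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. The log2 difference was −0.08 for Hoxa9 (SE 0.32, adjusted p = 0.88), −0.09 for Hoxa7 (SE 0.53, adjusted p = 0.917), 0.60 for Hoxa10 (SE 0.51, adjusted p = 0.405) and −0.33 for Mpo (SE 0.36, adjusted p = 0.526). Hoxa7, Hoxa9 and Hoxa10 did not pass in edgeR or DESeq2 either. HOXB genes were higher with NUP98-KDM5A in 3 of 3 cases (3 adjusted over the list alone, adjusted p = 0.00323), Hoxb3 at least 56.7-fold, Hoxb5 at least 21.5-fold and Hoxb4 with adjusted p = 0.0193, and 0.064 without NUP98-KDM5A replicate 3, its log2 difference going from 3.39 to 2.05 without artFG-KDM5A replicate 2. For Hoxb3 and Hoxb5, tested because they were high with NUP98-KDM5A, this direction was set by the filter, and with it part of the list result. Mast cell genes were higher in 21 of 25 cases (23 adjusted over the list alone, adjusted p = 2.04e-14), Cpa3 by 33.7-fold and Cma1 by 46.1-fold. Glycolysis and hypoxia genes were higher in 19 of 23 (22 adjusted over the list alone, adjusted p = 1.13e-09), Aldoc by 10.4-fold. Megakaryocyte and platelet genes were higher in 11 of 14 cases (11 adjusted over the list alone, adjusted p = 0.000107, and adjusted p = 0.167 with an estimated correlation), the integrin gene Itgb3 at 188 ± 32.2 against 1.35 ± 1.45. After quantile normalization 6 of these were higher and 1 lower, and the median went from 2.75 to 0.98. Rab27b and F2r of this list were abundant in the unmodified cultures (3547 and 1741), which were rich in mast cell transcripts. They read 425 and 375 with NUP98-KDM5A and 6.93 and 50.5 with artFG-KDM5A. The list result is therefore not separate from that of the mast cell genes, although Treml1, also higher, read 0 in unmodified cells. Arg1, an alternatively activated macrophage enzyme gene, read 8440 ± 377 against 57.6 ± 73.5, and H2-Ab1 was at least 187-fold higher. MYC and ribosome biogenesis genes were lower in 17 of 28 cases and 1, Ldha, was higher (20 and 1 adjusted over the list alone, adjusted p = 2.83e-11), Utp20 by 3.40-fold. Kdm5a was 12.3-fold, Cdkn2c 9.12-fold and Pbx3 7.36-fold lower. In all 2641 genes differed, 2003 higher and 638 lower, of which 1770 and 299 by at least 2-fold, and the Y-linked genes, H19 and Igf2 were among the higher. Without NUP98-KDM5A replicate 2 or 3 the count was 1668 or 1686, and without artFG-KDM5A replicate 2 it was 3490. Of the called genes 75.8% were higher, 47.8% after quantile normalization, and the median log2 change of all genes was 0.362, 0.323 with equal totals and −0.123 after quantile normalization.

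Most genes called for NUP98-KDM5A against unmodified cells had the same direction for artFG-KDM5A against artAA-KDM5A, a pair of comparisons without a shared library. Across 11009 genes, which are not independent replicates, the log2 changes of these comparisons had r = 0.720 and a covariance of 2.39. Of the genes called higher 847 were higher in both, against 203 for independent lists, and 1010 were lower in both against 265, while 40 went opposite ways. Of the 1387 genes higher with NUP98-KDM5A, 88.1% had the same sign in artFG-KDM5A against artAA-KDM5A, with a median of 1.54 (camera p = 2.21e-53 by limma, and p = 5.2e-07 with an estimated correlation), and of the 1247 lower genes 94.6%, with a median of −2.03 (p = 6.09e-57, and p = 3.44e-06 with an estimated correlation). Hoxa9, Mpo, S100a9 and Sox4 are among the former, and Cpa3, Kit and Gata1 among the latter. Over all 11009 genes, 42.4% had a positive and 57.5% a negative change in artFG-KDM5A against artAA-KDM5A. The shares of 88.1% and 94.6% therefore start from different base levels. The other arrangement without shared libraries, NUP98-KDM5A against artAA-KDM5A beside artFG-KDM5A against unmodified cells, had r = 0.541, a covariance of 2.02, 761 genes higher in both against 270, 881 lower in both against 297, and 223 opposite. In all 4 of these comparisons 662 genes were higher and 755 lower, of which 120 and 387 also differed between NUP98-KDM5A and artFG-KDM5A.

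Comparisons that share the unmodified libraries are correlated by these alone, by r = 0.499 to 0.5 in 100 simulations of unchanged groups. The simulations gave each gene the same spread in all 12 libraries. Unmodified libraries differed less from each other (median absolute log2 difference 0.229 to 0.267) than artFG-KDM5A replicate 2 did from its group (1.02 and 1.03). The simulated values may therefore overstate what sharing gives, and no conclusion is drawn from a value below them. NUP98-KDM5A and artFG-KDM5A, each against unmodified cells, had r = 0.715 and a covariance of 2.41, against 0.184 simulated. NUP98-KDM5A and artAA-KDM5A had r = 0.0230 and a covariance of 0.0290, against 0.185 simulated, with 37 genes higher in both, 71 lower in both and 122 opposite. For artFG-KDM5A and artAA-KDM5A these were r = 0.231 and 0.392 against 0.184, with 48 genes higher in both, 173 lower in both and 84 opposite. The 3 control libraries were not split, so part of any excess in these 3 pairs may come from them.

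**Figure D4:**
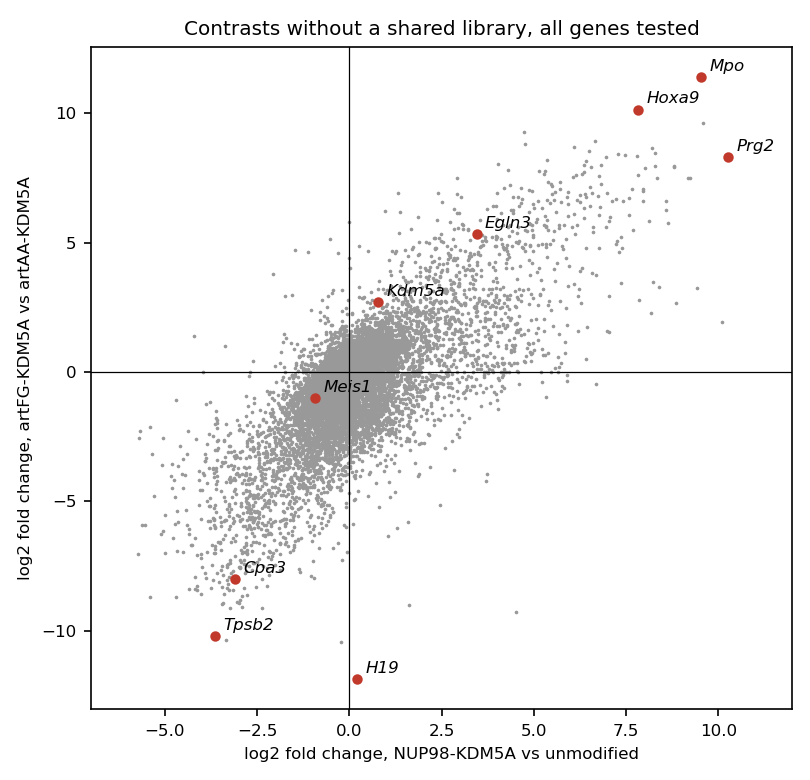
Log2 fold change of each of 11009 genes for artFG-KDM5A against artAA-KDM5A (vertical axis) and NUP98-KDM5A against unmodified cells (horizontal axis), 1 point per gene with key genes labelled. The comparisons share no library, and the points follow a rising diagonal with r = 0.720.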

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

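The tests of the whole mast cell remnant, of macrophage loss, of a shared batch and of the Kdm5a amount were chosen only after the results were seen, whereas the test of a minor share and the counts of splits were fixed beforehand.

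Mast cell transcripts remained with NUP98-KDM5A at a median of 14.6% of the unmodified level over 25 listed genes (range 2.25% to 2340%), while artFG-KDM5A lay far lower. A minor share of cells like those of the unmodified cultures may account for part of this, although the labels describe a sort. Of 112 other abundant genes lost with artFG-KDM5A, 7.14% (8 genes, 95% interval 3.13 to 13.6) fell below 0.5 of the mast cell ratio, under the 20% set beforehand for such a share. The interval counts genes as independent draws, which genes of the same libraries are not, and does not measure a spread between cultures. The median of the 112 genes was 14.4%. H19 (115%) and Igf2 (85.2%), whose near absence with artFG-KDM5A may reflect a different source of cells, are among the 112. As the whole of the remnant it met a counterexample: 3 of 131 abundant genes, Tpsab1 (2.25% of unmodified), Fcer1a (2.52%) and Camk2n1 (2.82%), lay in each NUP98-KDM5A library below 0.5 of the lowest ratio among Cpa3 (11.6%), Tpsb2 (8.01%) and Cma1 (9.17%). The bound of this test, 3 such genes, was also set after the results were seen and was only just met. Camk2n1 read 95.9 with artAA-KDM5A against 517 in unmodified cells, so its level also differed between cultures that were both rich in Cpa3. A smaller share and a lower expression within the cells both stay open.

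Glycolysis and hypoxia genes fell with both artificial constructs. Loss of macrophage-like or dendritic-like cells is a candidate explanation for artAA-KDM5A: the summed counts of 32 genes of those cells fell by 3150 (5853 to 2703) and those of 23 glycolysis genes by 27840 (49550 to 21710), a ratio of 0.113. A complete loss of those 32 genes would give no more than 0.21, under the bound of the test, so the ratio decides nothing and this explanation stays open. A culture or library batch shared by the artificial constructs also stays open: of 221 genes that passed in the same direction with both, 102 (46.2%) also did so with NUP98-KDM5A, against 11.6% for independent lists, but no label gives a batch and this value cannot tell a batch from the constructs. All these comparisons use the same unmodified libraries, so the lists are not independent. Part of the excess over 11.6% may come from that sharing. Oxygen supply and cell density, which the labels do not give, were not tested. Neither were transduction and sorting, which cannot be told apart from the constructs here.

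HOXA and granulocyte genes were high with artFG-KDM5A and low with artAA-KDM5A, whose Kdm5a counts differed 6.55-fold, so the amount of construct transcript is a possible explanation. Kdm5a was lower in NUP98-KDM5A than in artAA-KDM5A by −0.89 on the log2 scale (SE 0.18, limma adjusted p = 0.00291), yet 4 of 4 HOXA genes were higher there (highest adjusted p = 4.41e-06). This argues against the counted amount as the sole cause, but only as far as Kdm5a counts follow the construct. How construct reads are counted under Kdm5a could not be examined and may differ between constructs. Protein was not measured, and a threshold that differs between constructs stays open. A difference in the sex or source of the artFG-KDM5A cells, whose Y-linked genes, H19 and Igf2 are nearly absent, was not tested as an explanation and stays open.

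Each comparison has 10 splits of its 6 libraries into groups of 3, too few for a share under 0.05. In each, 1 split, the real one, gave as many genes as the groups did, with 2634 genes against at most 0 in the others for NUP98-KDM5A and unmodified cells, 4483 against 0 for artFG-KDM5A and unmodified cells, 377 against 0 for artAA-KDM5A and unmodified cells, 3955 against 1 for artFG-KDM5A and artAA-KDM5A, 2886 against 0 for NUP98-KDM5A and artAA-KDM5A, and 2641 against 0 for NUP98-KDM5A and artFG-KDM5A.

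Named genes that went opposite ways against unmodified cells, with the log2 difference of NUP98-KDM5A minus artFG-KDM5A by limma, were the following. Mgl2, Rbp4 and Hoxb3 have 2, 1 and 0 reads in the artFG-KDM5A libraries, so their fitted values depend on the pseudocount and give a direction, not a size. Mgl2, a macrophage lectin gene, differed by 9.35 (SE 0.61, adjusted p = 2e-06, against unmodified 5.47 and −3.88). Mmp13, a collagenase gene, differed by 8.15 (SE 0.48, adjusted p = 8.9e-07, 1.62 and −6.53). Rbp4 differed by 6.03 (SE 0.47, adjusted p = 6.8e-06, 2.20 and −3.83). Hoxb3 differed by 5.71 (SE 0.51, adjusted p = 1.71e-05, 4.12 and −1.59, the last with adjusted p = 0.107 without unmodified replicate 1 and turning to 0.01 after quantile normalization). Oasl2 differed by 5.68 (SE 0.58, adjusted p = 4.05e-05, 2.67 and −3.01). Mrc1 differed by 3.71 (SE 0.29, adjusted p = 7.06e-06, 2.78 and −0.93). Slc2a1, a glucose transporter gene, differed by 2.49 (SE 0.27, adjusted p = 6.8e-05, 1.69 and −0.80). Bax, an apoptosis gene, differed by −2.55 (SE 0.43, adjusted p = 0.00139, −1.32 and 1.23). Pbx3 differed by −2.83 (SE 0.30, adjusted p = 5.28e-05, −2.00 and 0.82, the last with adjusted p = 0.0465, and 0.135 without unmodified replicate 1).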

How the results depend on the processing

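Counts of genes moved with the fit, the test and the libraries used. With only the groups compared in the fit, 6009 genes passed for NUP98-KDM5A against unmodified cells (2634 in the main setting), 901 for artAA-KDM5A against unmodified cells (377), 2233 for artFG-KDM5A against artAA-KDM5A (3955), 4859 for NUP98-KDM5A against artAA-KDM5A (2886) and 1481 for NUP98-KDM5A against artFG-KDM5A (2641). With weights per library, a fit that gave a convergence warning, 6168, 4487 and 7855 passed for NUP98-KDM5A and artAA-KDM5A against unmodified cells and for NUP98-KDM5A against artAA-KDM5A, and DESeq2 gave 802 for artAA-KDM5A against unmodified cells. Leaving out 1 library gave 1874 (without NUP98-KDM5A replicate 3) to 4617 for NUP98-KDM5A against unmodified cells, 3623 to 5588 for artFG-KDM5A, 199 (without unmodified replicate 3) to 1336 for artAA-KDM5A, 3117 to 5138 for artFG-KDM5A against artAA-KDM5A, 2153 (without NUP98-KDM5A replicate 3) to 4817 for NUP98-KDM5A against artAA-KDM5A, and 1668 (without NUP98-KDM5A replicate 2) to 3490 for NUP98-KDM5A against artFG-KDM5A, each highest count being without artFG-KDM5A replicate 2. In comparisons of groups other than artFG-KDM5A, leaving out artFG-KDM5A replicate 2 changes no group mean. Those shifts therefore came through the shared estimate of spread. Arg1 in artAA-KDM5A against unmodified cells kept a log2 change of −6.96, while its limma adjusted p went from 0.0115 to 4.19e-07. The cause of the other shifts was not tested. With replicate number as a block the counts, in this order, were 2406, 4282, 278, 3657, 2631 and 2339.

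The correlation between NUP98-KDM5A against unmodified cells and artFG-KDM5A against artAA-KDM5A, 0.720, became 0.67 without a filter, 0.764 with a filter at 50 and 0.755 after quantile normalization, and 0.666 to 0.766 leaving out 1 library. The other pair without shared libraries, 0.541, gave 0.571 with a pseudocount of 5, 0.507 without a filter, 0.566 with a filter at 50, 0.594 after quantile normalization, and 0.491 to 0.588 leaving out 1 library. The median change of the genes higher with NUP98-KDM5A in artFG-KDM5A against artAA-KDM5A, 1.54, ran from 1.16 to 1.96 leaving out 1 library, and that of the lower genes, −2.03, from −2.50 to −1.42. List tests that passed, 88 in the main setting, were 50 with an estimated correlation and 82 to 93 leaving out 1 library.

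For named genes, 658 results under 25 alternatives gave 16384 values. Of these 15956 stayed called or stayed not called, 420 lost a call, 7 gained a call and 1 turned. Direction was compared only where a gene was called, and the size of the change was not compared. That 1 was Hoxb3 in artFG-KDM5A, which has 0 reads of it, against unmodified cells, a fitted −1.59 that depends on the pseudocount in the main setting and 0.01 (adjusted p = 0.991) after quantile normalization. Named genes that passed and lost the call without some library numbered 7 of 110 for NUP98-KDM5A, 6 of 117 for artFG-KDM5A and 21 of 64 for artAA-KDM5A against unmodified cells, 11 of 115 for artFG-KDM5A against artAA-KDM5A, 9 of 118 for NUP98-KDM5A against artAA-KDM5A and 9 of 105 for NUP98-KDM5A against artFG-KDM5A.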

Other observations

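Some lymphoid, stromal and platelet genes were higher with NUP98-KDM5A than in unmodified cells. Of 9 lymphoid genes 5 were higher than in unmodified cells and 1, Gzmb, was lower (5 and 2 adjusted over the list alone, limma adjusted p = 0.0926), with the granule gene Nkg7 at 544 ± 47.2 against 3.60, the T cell surface gene Thy1 75.8-fold higher and Gzmb at 138 against 498 (adjusted p = 0.0214, and 0.0801 without NUP98-KDM5A replicate 1). After quantile normalization 3 lymphoid genes were lower, and 2 without artFG-KDM5A replicate 2. Of 3 stromal and endothelial genes Pdgfrb and the fibronectin gene Fn1 (14.7-fold) were higher (3 adjusted over the list alone, adjusted p = 0.00863, and adjusted p = 0.0569 with an estimated correlation). Of 3 fetal hepatocyte genes 1, the retinol carrier gene Rbp4, was higher than in unmodified cells (3 adjusted over the list alone, adjusted p = 0.0878), and 2 were after quantile normalization or without artFG-KDM5A replicate 2. Megakaryocyte and platelet genes split, 4 of 14 higher and 4 lower (5 and 4 adjusted over the list alone, adjusted p = 0.653, median 0.80, turning to −0.23 after quantile normalization), with the platelet chemokine gene Ppbp 192-fold higher and the integrin gene Itga2b 7.01-fold lower. With artFG-KDM5A erythroid genes were higher in 6 of 14 cases and 2, Gata1 and Icam4, were lower (9 and 2 adjusted over the list alone, adjusted p = 0.0654), and stem and progenitor genes went up in 10 of 26 and down in 11 (10 and 12 adjusted over the list alone, adjusted p = 0.653), the adhesion receptor gene Adgrg1 by 20.6-fold upwards.

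Ribosomal protein genes rose with NUP98-KDM5A in 14 of 78 cases and fell in 1 (14 and 1 adjusted over the list alone, adjusted p = 2.09e-05, and adjusted p = 0.298 with an estimated correlation), Rpl6 by 1.86-fold, and in 37 cases with equal totals, 34 after quantile normalization and 26 without artFG-KDM5A replicate 2. Amino acid and unfolded protein stress genes went both ways with artFG-KDM5A, 8 of 22 higher and 5 lower (9 and 5 adjusted over the list alone, adjusted p = 0.198), with the serine synthesis gene Psat1 4.43-fold and the asparagine synthetase gene Asns 4.32-fold higher. With artAA-KDM5A 2 of this list fell, Vldlr and Hsp90b1 (8 adjusted over the list alone, adjusted p = 3.19e-05), 4 after quantile normalization and 7 without artFG-KDM5A replicate 2. The Hsp90b1 call (adjusted p = 0.012) was lost without any of 3 libraries, with the highest adjusted p = 0.077 without artAA-KDM5A replicate 3. Interferon response genes fell with artFG-KDM5A in 13 of 24 cases and rose in 2 (13 and 2 adjusted over the list alone, adjusted p = 0.0736), and rose in 4 after quantile normalization. Replication-dependent histone genes rose with artFG-KDM5A in 4 of 28 cases and fell in 2 (3 and 2 adjusted over the list alone, adjusted p = 0.188), and rose in 12 after quantile normalization and in 8 without artFG-KDM5A replicate 2.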
